A study of Mus musculus with 4 samples.

How the data were processed

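METTL3 ChIP-seq was carried out in C57BL/6 mouse embryonic stem cells grown with LIF and the inhibitors CHIR99021 and PD0325901, per the labels' protocols. Chromatin was fixed with 1% formaldehyde and sonicated to 200 to 500 bp, and 1% of it was kept as input. The 4 libraries fell into 2 groups, METTL3 IP and input, with 2 replicates each, as their titles state. The titles mark all 4 as WT, for wild type. The submitters' processing notes name CASAVA, Trimmomatic 0.38, Bowtie 1.2.2 and HOMER, and the genome build mm10. They give no role, order or settings for these tools, and alignment settings are not given in the sources used here.

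The 2 IP libraries each had a peak list, and the input libraries entered only through the caller's input columns. Per the file headers, peaks were called per IP library with HOMER's findPeaks in its factor style, each against the input of the same number, and not on pooled replicates. Per the file headers, the false discovery rate was 0.001, which set a minimum of 14 tags for a putative peak, the Poisson p-value required over input and over the surrounding 10 kb was 0.0001, the fold required over each was 1, and at most 1 tag per position was counted. A fold requirement of 1 is lenient, since it lets any excess with a low enough p-value through. The putative peaks numbered 804 in replicate 1 and 778 in replicate 2. Of these, 442 (55.0%) and 492 (63.2%) were removed by the comparison with input, and 9 and 5 by the local comparison.

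The deposited normalised tag count is a signal in IP tags scaled to a library of 10000000 tags. The authors' total tags column is a count of IP tags in replicate 1 and a scaled signal in replicate 2, and the control column is input signal scaled by the caller in replicate 1 and unscaled input tags in replicate 2. The deposited focus ratio is the fraction of a peak's tags that lie on the expected strand side of its centre. The findPeaks score and the fold over input, a ratio, are the authors' own values per peak, as are the p-values deposited beside them. These were used to describe, rank or filter peaks within a list. Where a peak had no input tag, the caller put a small count in its place, so its fold is not a bound and its rank by fold rests on that count. Such peaks numbered 23 of 353 (6.52%) in replicate 1 and 62 of 281 (22.1%) in replicate 2.

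Whole tags were recovered from the scaled columns by dividing them by the value of a single tag. The score never fell below the minimum of 14 tags, but the IP tags recovered for a listed peak went down to 12 in both replicates. The largest distance from a whole number was 0.11 tags for IP and 0.046 tags for input. A fold's 95% interval is the exact conditional binomial interval of IP and input tags, with library totals as offsets. With no input tag, a floor was computed with 3 input tags per library in place of 0, which leaves out IP counting error, and the lower end of the exact interval, which includes it, is given beside it. Depth differed more between inputs, about 24800000 and 14900000 tags, than between IPs, 22246555 and 21793898, so folds of replicate 2 rest on fewer input tags. A median peak held 18 and 19 IP tags and 3 and 1 input tags. Shares have exact Clopper-Pearson 95% intervals.

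Coordinates are on mm10, 1-based. Genes came from a RefSeq table of the same assembly that gives the start, end and type of each gene. Strand, exons, transcription start sites and sequence were not used here. Several tests therefore differ from the plan. Location was scored as within 1 kb of either gene end, elsewhere in a gene, or intergenic. The gene-list test used the gene and 5 kb on both sides. Random intervals were placed between the first and last annotated gene of the same chromosome without excluding assembly gaps, and the sequence composition of peaks was not analysed here.

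Shared peaks overlapped by at least 1 bp. The overlap, location, clustering and gene-list tests used 1000 random placements of the peaks with the same chromosome and width. Counts per chromosome were tested with the exact binomial test over 21 chromosomes, shares in the upper and lower of 3 equal parts of a list with Fisher's exact test, and correlations with 100000 permutations. Adjusted p-values are Benjamini-Hochberg values over the 3 location classes, the 21 chromosomes or the 10 gene lists, with a threshold of 0.05. The matched test within 100 kb drew 10000 random sets of protein-coding genes of similar length and gene density for 8 lists. IP and input tags in the shared peaks were also fitted with edgeR's quasi-likelihood test on the recovered tags and library totals, with and without the replicate number as a block. Local tag density was the caller's IP tags over the local fold, as a median over the peaks of a chromosome.

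The tests, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The rule took the first 25 genes by the lower of both folds among shared peaks, within the gene or 10 kb. It also took list members with a shared peak, up to 4 members per list with a peak in 1 replicate alone, and the 3 peaks of highest fold in each replicate. Of the listed names, Dux and Rn45s had no match in the gene table. The genes named for windows beyond 5 kb and for groups of neighbouring peaks were chosen after their values were seen. Alternatives covered the fold threshold, the overlap rule, the placement rule, merging of neighbours within 10 kb, gene windows, and leaving out each replicate. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16. On simulated lists of the same size, 100 of 100 planted shared peaks and 4 of 4 planted list genes were found, with 0 of 9 other lists called. In 20 random lists, drawn over the same chromosome spans as the tests use, 0 chromosomes and 0 location classes were called. Such lists check the computation and cannot show the effect of unassembled or unmappable stretches. In 195 simulated peaks, edgeR found 97 of 97 raised peaks without the block and 96 with it, and 0 of 98 unchanged ones in both fits.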

Results

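METTL3, the catalytic subunit of the nuclear enzyme that writes N6-methyladenosine (m6A) on RNA, was mapped on the DNA of mouse embryonic stem cells by chromatin immunoprecipitation and sequencing (ChIP-seq). The study asked where METTL3 sits on the genome of these cells. The 4 libraries were 2 immunoprecipitations (IP) with a METTL3 antibody and 2 inputs, which are sonicated chromatin without antibody. IP replicate 1 held 22246555 tags and IP replicate 2 held 21793898 tags. The inputs held about 24800000 and 14900000 tags, recovered from the caller's scaling of the input columns in replicate 1 and of the IP columns in replicate 2. Each IP was called against the input of its own number. The labels do not say that the replicates came from separate cultures, so the spread between them may be technical. Intervals below cover counting error only. No arm without METTL3 and no control antibody was analysed here, so each peak was compared with input and with the other replicate.

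Many of the METTL3 peaks were the same in both replicates. The caller listed 353 peaks in replicate 1 and 281 in replicate 2, or 317 ± 50.9 (SD, n = 2). Shared peaks numbered 195, which was 55.2% of the peaks of replicate 1 (exact 95% interval 49.9 to 60.5%) and 69.4% of those of replicate 2 (63.6 to 74.7%). Summed over the shared peaks, which were called because IP exceeded input there, IP tags exceeded scaled input 10.6-fold in replicate 1 (95% interval 9.76 to 11.6) and 10.7-fold in replicate 2 (9.62 to 12). With a fold of at least 8 in both lists, the shares were 48.0% and 42.6%. In the upper of 2 equal parts of each list by score, they were 60.8% and 76.4%. The tallest shared peaks included a site in Tet2, which encodes a 5-methylcytosine dioxygenase, and sites in Fryl and Fam174a. Against 1000 random placements of the other list, in which at most 1 peak overlapped, the overlap had a one-sided permutation p of 0.001 for both replicates, the smallest these placements can give. All peaks together held 0.0362% of the IP tags of replicate 1 and 0.0304% of those of replicate 2.

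Ranked by the caller's fold, which puts a small count in place of a zero input, the first shared peaks lay in or near 25 genes, of which 16 were protein-coding and 6 were long non-coding RNA genes. Heights are the caller's normalised IP tags, scaled to a library of 10000000 tags, as mean and SD over both replicates, with mm10 positions from replicate 1. First by rank was a peak 8.54 kb from the long non-coding RNA gene E330032C10Rik (chromosome 17, 73262680 to 73262850), at 35.2 ± 0.141 (SD, n = 2) against 0.403 ± 0.570 input tags on the same scale. It was followed by peaks inside Wdr7 (chromosome 18, 63924623 to 63924793; 15.4 ± 2.76), inside the zinc finger gene Zfp462 (chromosome 4, 54987250 to 54987420; 9.54 ± 0.141) and inside Dmd, the dystrophin gene (chromosome X, 85053791 to 85053961; 7.74 ± 2.04). The Zfp462 and Dmd peaks had no input tag in either replicate. With 3 input tags per library in place of 0 and IP counting error left out, IP was at least 7.81-fold and 4.77-fold above input at Zfp462, and at least 5.20-fold and 4.55-fold at Dmd. With that error included, their exact 95% intervals began lower, at 5.81 and 3.55 and at 3.70 and 3.37, so their places above peaks with measured input, such as that in Fam174a, rest on the substituted count.

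Several of these genes held tall peaks. The peak inside Fam174a (chromosome 1, 95326973 to 95327143) reached 34.8 ± 1.77 (SD, n = 2), and the one inside Fryl (chromosome 5, 73219816 to 73219986) reached 35.4 ± 4.31. A peak shared by the overlapping genes Cdc37l1 and Ak3, the latter a mitochondrial adenylate kinase, stood at 26.1 ± 3.82 (chromosome 19, 29008160 to 29008330). Tnfrsf19, a member of the tumour necrosis factor receptor family, had a peak of 35.6 ± 1.06 at 5.68 kb from the gene (chromosome 14, 60957983 to 60958153). Lower peaks lay 0.486 kb from Ogt, which encodes the O-GlcNAc transferase (7.94 ± 1.49), inside Ank3, the ankyrin G gene, together with Gm33361 (8.58 ± 3.71), and inside Pfdn1, a prefoldin subunit gene (8.41 ± 1.09). Pla2g10, Bcl2l15, Gm12031, Gm30847 and Gm32130 held peaks of 9.77, 7.97, 9.54, 13.8 and 20.4 normalised IP tags, and Gm14230 with LOC115486128 one of 16.8. Peaks near a gene stood at the small nuclear RNA gene Gm25186 (8.46 kb, 18.1), the pseudogene Gm13130 (7.94 kb, 11.6), the aspartate transfer RNA gene n-TDgtc1 (5.99 kb, 13.6) and the renin gene Ren1 (9.98 kb, 8.19).

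Among the first 10 by rank, 3 peaks had no gene within 10 kb. One of them, on chromosome 15 (62012697 to 62012867; 20.2 ± 5.80, n = 2), lay 22.3 kb from Myc. The others were on chromosome 6 (65270805 to 65270975; 40.6 ± 4.88) and chromosome 2 (9535478 to 9535648; 7.71 ± 1.82). The 3 peaks of highest caller's fold in replicate 1 were in 6030442K20Rik (chromosome 1, 132471153 to 132471323; 104.8-fold, 95% interval 18.4 to 4180), 4.74 kb from Jam2 (at least 15.6-fold by the same floor, 95% interval from 12.1) and 75.8 kb from Glis3 on chromosome 19 (28182920 to 28183090; at least 13.0-fold, interval from 10.0). In replicate 2 they were those at Fryl, E330032C10Rik and Wdr7, at least 19.1-fold, 17.5-fold and 8.64-fold by that floor with 95% intervals from 15.2, 13.9 and 6.69, which do not rank them above peaks with measured input such as that in Fam174a (24.9-fold). All 6 were shared, but the 3 leading folds of replicate 1 were lower in replicate 2. There the peak in 6030442K20Rik was 10.1-fold (95% interval 4.47 to 28.3) and that near Jam2 10.9-fold (2.78 to 93.95). The one near Glis3 was 3.68-fold (1.40 to 12.2).

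Genes of the pluripotency network, a list of naive and core factors of embryonic stem cells, had more METTL3 peaks than chance placed there. Of 25 members, 3 had a shared peak in the gene or within 5 kb: Tet2, Esrrb and Tfcp2l1. The Tet2 peak (chromosome 3, 133524843 to 133525013) measured 41.2 ± 10.5 (SD, n = 2) against 2.69 ± 0.954 in input, 16.7-fold in replicate 1 (95% interval 6.86 to 53.0) and 14.5-fold in replicate 2 (6.00 to 45.4). Inside Esrrb, an orphan nuclear receptor gene of the naive state, the peak (chromosome 12, 86501759 to 86501929) measured 22.9 ± 3.18 against 1.95 ± 1.05. At Tfcp2l1, a transcription factor gene of the same state, it stood 2.21 kb from the gene (chromosome 1, 118625546 to 118625716) and measured 9.08 ± 0.509. Random placement gave 0.08 members on average, for a one-sided permutation p of 0.001, the smallest the placements can give, and a Benjamini-Hochberg adjusted p of 0.01 over 10 lists. Nanog and Tbx3 held a peak in replicate 2 alone, of 7.34 normalised IP tags (5.46-fold, 1.28 to 48.9) and 6.42 (no input tag, at least 3.18-fold with 3 input tags in its place, 95% interval from 2.26).

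Farther out, peaks surrounded more of this network. Within 100 kb, a distance chosen after the peaks had been seen, 9 of the 25 genes had a shared peak, against 0.624 in random gene sets matched on length and gene density. Beyond Tet2, Esrrb and Tfcp2l1 these were Zfp42 (13.7 kb away; 21.4 ± 0.919, n = 2), Myc (22.3 kb), Klf5 (23.1 kb; 16.6 ± 5.87), Prdm14 (28.3 kb; 20.4 ± 4.17), Klf4 (49.5 kb; 7.95 ± 0.205) and Sox2 (92.9 kb; 20.0 ± 6.08). The peak near Klf5 had Pibf1 as its nearest protein-coding gene, and the others had the gene named here. Klf4 had 3 shared peaks within that distance. The highest of the 10000 matched sets held 5 such genes, for a permutation p of 0.0001, the smallest the sets can give, and an adjusted p of 0.0008 over the 8 lists with protein-coding members. Each replicate alone gave 12 of 25 genes, with the same adjusted p, but among them were the 9 genes with a shared peak. In replicate 2, the peak in Nanog also lay within 100 kb of Dppa3 and counted for both genes. Pou5f1, the gene of OCT4, had its nearest shared peak 1910 kb away, and Nanog 3940 kb away.

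**Figure D1:**
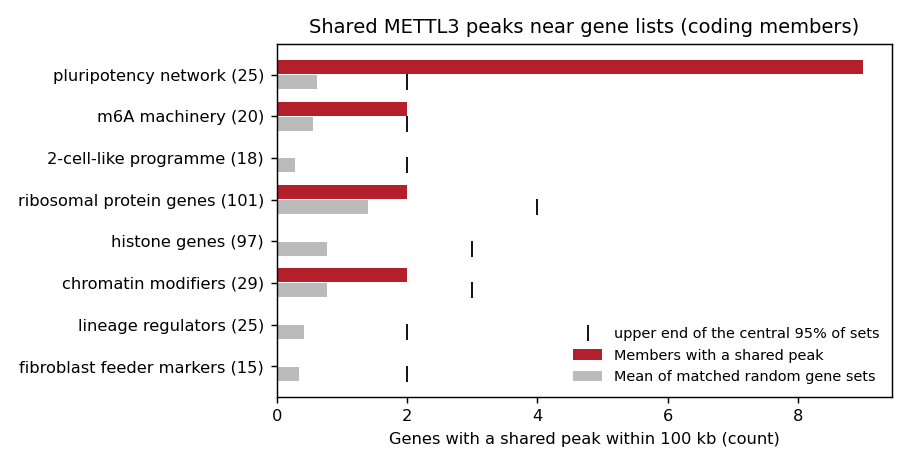
Bars give the number of genes per list with a shared METTL3 peak within 100 kb (red) and the mean of 10000 random gene sets matched on length and gene density (grey), with the upper end of the central 95% of the sets as a tick; the number of protein-coding members is in parentheses. The pluripotency network stands at 9 of 25 genes against 0.624.

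The genes of METTL3 itself and of its partner METTL14 held shared peaks. No other of the 20 listed m6A genes had a shared peak within 5 kb. The shared peak in Mettl3 (chromosome 14, 52297546 to 52297716) measured 12.5 ± 1.41 (SD, n = 2) against 1.75 ± 1.52 in input. It was 4.78-fold over input in replicate 1 (95% interval 2.06 to 12.9) and 17.1-fold in replicate 2 (2.79 to 700). Replicate 2 alone had another peak inside Mettl3 (52299919 to 52300087), with 14 IP tags and no input tag. With 3 input tags in place of 0 it was at least 3.18-fold, with a 95% interval from 2.26. Mettl14 held 3 peaks on chromosome 3, starting at 123371321, 123372546 and 123380179, of 12.9 ± 0.778, 6.58 ± 0.417 and 12.7 ± 4.04. These 2 of 20 writers, erasers and readers compared with 0.125 by random placement (one-sided permutation p = 0.008, adjusted p = 0.04). The call did not pass in replicate 1 alone (adjusted permutation p = 0.14) or in replicate 2 alone (0.055), nor within 100 kb (0.44). With a fold of at least 8, 1 gene was left and the call was lost (adjusted permutation p = 0.27). Within 20 and 50 kb it was lost as well (0.07 and 0.095 by random placement). Whether the peaks fall on exons was not analysed here.

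**Figure D2:**
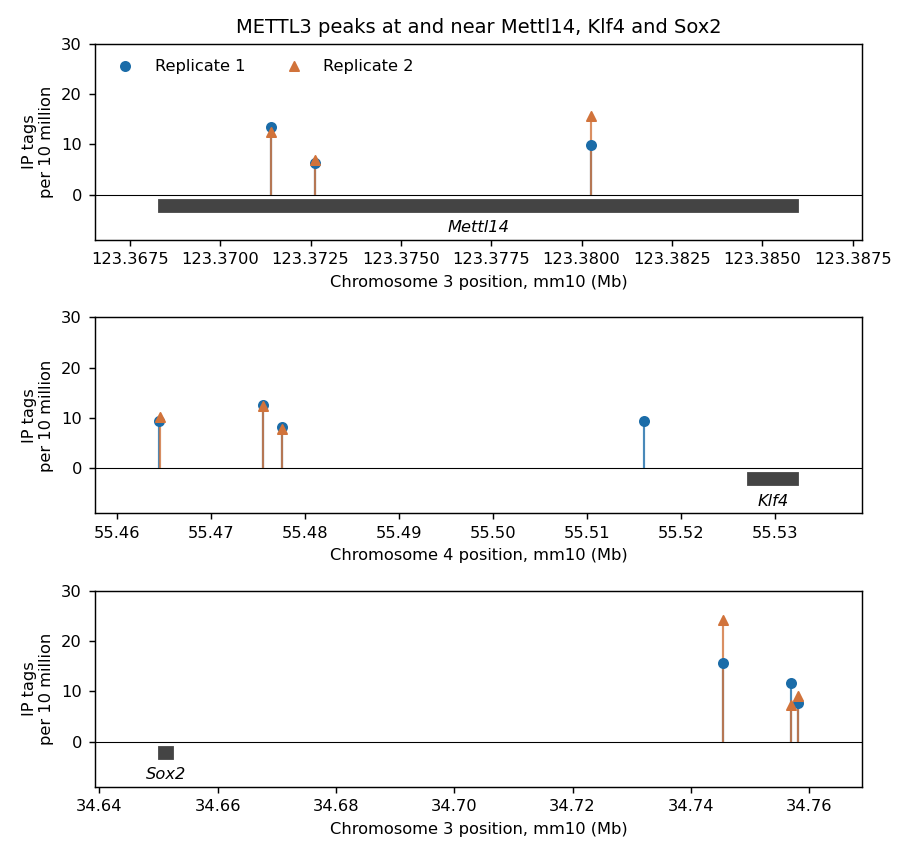
Normalised IP tags of each peak, scaled to a library of 10000000 tags (vertical axis), against its mm10 position (horizontal axis) in replicate 1 (blue circles) and replicate 2 (orange triangles), with the gene as a dark bar. Mettl14 holds 3 peaks found in both replicates. The shared peak nearest to Klf4 lies 49.5 kb from the gene, with a peak of replicate 1 alone closer to it. The shared peak nearest to Sox2 lies 92.9 kb from that gene.

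No other list passed. Of 2344 small nuclear and nucleolar RNA genes, 1 had a shared peak within 5 kb (Gm22150, 4.42 kb away, 9.77 ± 0.467, n = 2) against 1.74 by random placement, and Gm26479 had one in replicate 1 alone. Shared peaks were absent within 5 kb of 101 ribosomal protein genes, 97 histone genes, 20 abundant non-coding RNA genes and 29 chromatin modifiers. They were also absent there for 25 lineage regulators, 15 fibroblast feeder markers and 20 genes of the 2-cell-like programme or linked to endogenous retroviruses. For these lists random placement gave 0.016 to 0.161 members, too few for an absence to be detectable. Dnmt3a, a de novo DNA methyltransferase gene, had a peak of 12 IP tags in replicate 1 alone (4.46-fold, 1.20 to 24.6). Within 100 kb the chromatin modifiers Jarid2 and Kdm5b had a shared peak (2 of 29 genes against 0.774, adjusted permutation p = 0.48), and none of the lineage regulators had one (0 of 25 against 0.413).

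Peaks were spread over genes and intergenic DNA much as randomly placed intervals were. Within 1 kb of a gene end lay 7.12% ± 0.0287 (SD, n = 2) of peak centres, elsewhere in a gene 45.6% ± 0.637, and between genes 47.3% ± 0.666. Random placement gave 6.24%, 44.4% and 49.4%. Among the shared peaks 5.13% lay within 1 kb of a gene end, and 94 of 195 overlapped a gene. Shared peaks outside protein-coding genes numbered 112 and lay a median of 22.9 kb from the nearest one. Adjusted two-sided permutation p values ran from 0.63 to 0.84 in the separate replicates and were 0.91 in the shared peaks. Gene ends were not split into starts and terminators, and exons and introns were not told apart.

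The heights of shared peaks ran together in both replicates, with Tet2 at 33.7 and 48.6 normalised IP tags, Esrrb at 20.7 and 25.2 and Mettl3 at 13.5 and 11.5. Across the 195 shared peaks the log2 heights correlated with Pearson's r of 0.851 and Spearman's rho of 0.755 (permutation p = 1e-05 for both, the smallest the test can give). Peaks are not independent replicates. Without the 2 peaks farthest from the median, r was 0.837. The SD of the log2 difference between replicates was 0.36, and 175 peaks (89.7%) lay within 1.5 times of each other. The caller's fold over input did not correlate (r = 0.00923, permutation p = 0.9), with medians of 3 input tags per peak in replicate 1 and 1 in replicate 2.

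**Figure D3:**
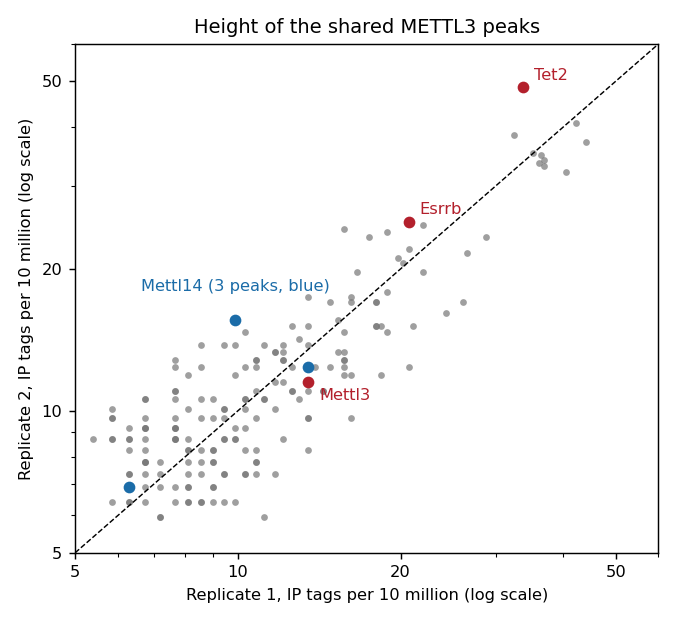
Height of each of the 195 shared peaks in replicate 1 (horizontal, log scale) and replicate 2 (vertical, log scale), in normalised IP tags (library of 10000000 tags); the dashed line marks equal heights. The Tet2, Esrrb and Mettl3 peaks are in red and the 3 Mettl14 peaks in blue, and Pearson's r of the log2 heights is 0.851.

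Peaks of high fold were found again more often than those of low fold in replicate 1. There 76 of the 117 peaks of highest fold, the upper part of 3 equal parts of the list, were shared (65.0%, exact 95% interval 55.6 to 73.6%), as at 6030442K20Rik and Jam2, against 45 of the 117 of lowest fold (38.5%, 29.6 to 47.9%; Fisher's exact test, two-sided, p = 7.97e-05). In replicate 2, where Fryl and E330032C10Rik led, the shares were 71.0% and 66.7% of 93 peaks each (Fisher's exact test, p = 0.635), and the difference between replicates was not tested. Ranked by normalised tag count, the upper part exceeded the lower part by 62.4 percentage points in replicate 1 and 57.0 in replicate 2. Peaks found in 1 replicate alone had a median of 15 IP tags in both lists, against 23 and 22 in shared peaks.

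Chromosomes 6 and 8 held more peaks than their length gave in replicate 1, and chromosomes X and Y held fewer in both replicates. Chromosome 8 had 38 peaks against 16.8 expected in replicate 1 and 24 against 13.4 in replicate 2 (exact binomial test, two-sided, adjusted p = 8.09e-05 and 0.0485). Chromosome 6 had 32 against 19.5 in replicate 1 (exact test, adjusted p = 0.0285) and 16 against 15.5 in replicate 2 (0.896). Chromosome X had 6 against 22.2 and 4 against 17.7 (exact test, adjusted p = 0.000676 and 0.0037), and chromosome Y 2 against 11.8 and 1 against 9.41 (0.00672 and 0.0142). Chromosome 7 had 8 against 18.9 in replicate 1 and 10 against 15.1 in replicate 2 (exact test, adjusted p = 0.0285 and 0.517). In the shared peaks the counts were 11 on chromosome 6 against 10.8 and 11 on chromosome 8 against 9.32, while X (3 against 12.3) and Y (0 against 6.55) stayed low (exact test, adjusted p = 0.0296 for both).

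Around the peaks, the median IP tag density in the local window was 1.41 ± 0.0092 (SD, n = 2) times that of other autosomes on chromosome 6 and 1.35 ± 0.049 times on chromosome 8. The other 17 autosomes ranged from 0.936 to 1.09, and chromosome X stood at 0.529 ± 0.041. With a fold over input of at least 8, which keeps 179 of the peaks of replicate 1, none of its chromosomes passed, with chromosome 8 at 1.75 times the expected count, 6 at 1.11, 7 at 0.416 and X at 0.354, while in replicate 2 chromosomes 8 (2.19 times; exact test, adjusted p = 0.016) and Y still passed and X did not (0.315 times, 0.0573). Expected counts used the span from the first to the last annotated gene, with no correction for unassembled or unmappable stretches.

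**Figure D4:**
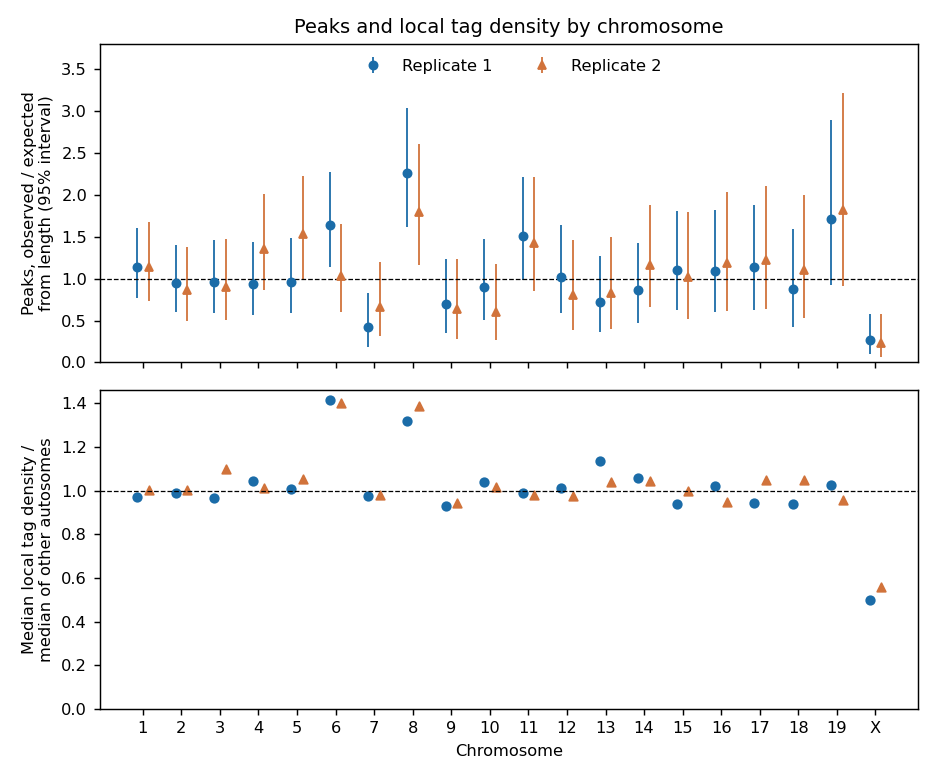
Upper panel, peaks observed over peaks expected from chromosome length, with exact 95% intervals; lower panel, median local IP tag density around peaks relative to other autosomes; horizontal axis, chromosome; blue circles, replicate 1; orange triangles, replicate 2. Chromosomes 6 and 8 stand at 1.41 and 1.35 in mean density and X at 0.529.

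A small share of the METTL3 peaks lay in groups, some at protein-coding genes and some farther from them. Within 10 kb of another shared peak were 14 of the 195 shared peaks (7.18%), in 6 groups. These included the 3 peaks in Mettl14, 2 in Thada (15.2 and 36.3 normalised IP tags) and 2 at Plekhf2. For the others, the distance runs from the gene to the nearest edge of the group. Near Kat6b, a histone acetyltransferase gene, a group of 3 peaks lay 12.8 kb away (chromosome 14, 21474656 to 21486463). Groups of 2 peaks lay 49.5 kb from Klf4 and 104 kb from Sox2. In the separate lists the shares were 5.67% in replicate 1 against 0.284% by random placement and 7.12% in replicate 2 against 0.245% (one-sided permutation p = 0.001 for both, the smallest the placements can give).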

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

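The counts below come from peaks on unplaced scaffolds, which entered no test of genes, location or chromosomes, and each was above its input. On the scaffold JH584304, replicate 1 had a peak with 77 IP tags and 52 input tags, 1.65-fold over scaled input (95% interval 1.15 to 2.4). On the scaffold GL456387, replicate 2 had a peak with 14 IP tags and 1 input tag, 9.55-fold (1.45 to 404). Neither was shared by the other replicate.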

How the results depend on the processing

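Gene windows beyond 5 kb, matched gene sets, the gene lists in single replicates, the location of shared peaks and the overlap without chromosomes 6 and 8 were tests chosen after the data were seen. Of 176 alternatives, 155 kept the direction and the side of the threshold, or stayed within the spread or 1.5 times for counts. Among them were 16 of 16 for the overlap of replicates, 21 of 21 for location and 93 of 102 for gene lists. All 9 changes among gene lists fell in the m6A list. Most of the other lists had few or no members with a peak and low expected counts, so their calls could hardly change. With a fold of at least 8 in both lists the overlap fell to 48.0% of replicate 1 and 42.6% of replicate 2, from 55.2% and 69.4%, and stayed past the threshold. In the upper of 2 equal parts of each list by score, it rose to 60.8% and 76.4%. Ranking by score or by normalised tag count gave a difference between the upper and lower parts of the list of 59.1 and 57.0 percentage points in replicate 2, past the threshold that 4.30 by fold did not reach. Correlating fold over input in place of height gave r = 0.0092 and rho = -0.021. With a fold of at least 8, replicate 1 kept 179 peaks and had 0 chromosomes past the threshold, with chromosome 8 at 1.75 times expectation against 2.26 and chromosome 6 at 1.11 against 1.64, while replicate 2 had 2, with chromosome 8 at 2.19 times against 1.79. The m6A list then had 1 gene (adjusted permutation p = 0.27). The m6A list kept 2 genes without replicate 1 and 2 without replicate 2 (adjusted permutation p = 0.05 and 0.11), in other random placements than those that gave 0.055 and 0.14. With windows of 20, 50 and 100 kb it had 2, 2 and 2 genes, with adjusted permutation p = 0.07, 0.095 and 0.22 by random placement and 0.088, 0.2 and 0.44 against matched gene sets, where 5 kb gave 0.039. The expected count rose with the window, from 0.125 to 0.448 by random placement at 100 kb. The cause of the other changes was not tested.

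Depth limits the folds, because a median peak had 3 input tags in replicate 1 and 1 in replicate 2. Between IP and input in the shared peaks, edgeR's quasi-likelihood test called 195 of 195 peaks without and 195 with the replicate block, on peaks chosen for an IP excess. Differences between replicates correlated at 0.1 between IP and input. With so few input tags per peak, this value cannot tell whether the numbers pair the libraries. Sequence composition was not run.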

Other observations

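Tests of input and focus ratio at Mettl3 and Mettl14, and of local tag density, input tags and sharing on chromosomes 6 and 8, the test of the other m6A genes and the comparison of pluripotency with lineage genes, were chosen after the result was seen, as was the distance of 100 kb. Peaks ranked by height rather than by fold brought in other genes, chosen after their values were seen. By the mean of both replicates, the tallest shared peak lay in 6030442K20Rik, at 41.5 ± 1.06 normalised IP tags (SD, n = 2). The Tet2 peak was close to it, at 41.2 ± 10.5. One in Thada on chromosome 17 (84355131 to 84355301) measured 36.3 ± 5.94, one in Epb41l4a on chromosome 18 (33836030 to 33836200) 34.9 ± 2.76, and one 2.27 kb from Ubqln4, a ubiquilin gene, 24.1 ± 3.47. A peak 20.0 kb from Foxd3, a forkhead transcription factor gene of pluripotent and neural crest cells, measured 35.4 ± 2.05 (chromosome 4, 99636084 to 99636254). A peak 8.22 kb from Jarid2, a partner of Polycomb repressive complex 2, measured 11.8 ± 1.13.

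On chromosome Y, replicate 1 had 2 peaks, 2.6-fold (95% interval 1.38 to 5.13) and 3.72-fold (1.44 to 11.3) over input, and replicate 2 had 1 peak, 3.41-fold (1.28 to 11.4). None was shared.

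The first pattern was the peaks near pluripotency genes. Gene length and gene density did not account for it, since 9 genes with a shared peak within 100 kb compared with 0.624 in matched sets (adjusted permutation p = 0.0008). Extra copies of chromosomes 6 and 8 could not account for it either, since 8 of these genes lie among the 21 members on other chromosomes. An equal preference for developmental regulators of any kind was argued against for the lineage list alone, and only within 100 kb. That distance was chosen after the peaks had been seen. There 0 of 25 lineage genes had a shared peak (Fisher's exact test against 9 of 25, two-sided, p = 0.00163). Within 5 kb the counts were 3 of 25 pluripotency and 0 of 25 lineage genes, a difference that was not tested. A weaker preference stays open, since 0.413 lineage genes were expected within 100 kb. Sall1 and Pax2, outside the list, had shared peaks 23.5 and 27.0 kb away. A candidate explanation, not tested here, is METTL3 at distal regulatory elements active in these cells. Nonspecific capture of open chromatin stays open too, since no control antibody or METTL3-deficient library was analysed here.

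The peaks in Mettl3 and Mettl14 formed another pattern. A regional signal around m6A genes stays open: the 2 genes of the list with a shared peak within 100 kb were Mettl3 and Mettl14 themselves, but matched sets gave 0.552, too few for the absence at the other genes to count (one-sided exact binomial p = 0.6). Construct or cDNA in IP and input alike stays open: input tags were 0.811 times those expected at the mean of shared peaks, but peaks with raised input had been removed by the caller, so a low count was set beforehand. Library titles read WT throughout, which does not tell whether such sequence entered the libraries. Sequence from a construct or cDNA in the IP libraries alone also stays open without exons. The focus ratio of the 4 shared peaks in these genes, at percentile 72.8 of shared peaks, does not decide it.

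The third pattern was the excess on chromosomes 6 and 8. Extra copies of both chromosomes in some or all of the cultured cells may account for it. Local tag density there was 1.38 ± 0.032 (SD, n = 2) times that of other autosomes (permutation p = 0.0001 in each replicate, the smallest the test can give). That p-value treats peaks as independent, on 2 chromosomes picked after their excess was seen. On chromosome 6 the density ratio was 1.41 in replicate 1 and 1.40 in replicate 2. Yet replicate 2 had no excess there, with 16 peaks against 15.5 expected (exact test, adjusted p = 0.896). Denser METTL3 binding beyond this density stays open: peaks per megabase were 0.738 times those elsewhere after the tag threshold was raised in proportion (0.85 with a 95% interval of 0.562 to 1.24, and 0.627 with 0.371 to 1.0), but that step also removes weak bound sites. At a fold of at least 8, chromosome 8 held 1.75 and 2.19 times the expected peaks (exact test, adjusted p = 0.175 and 0.016) and chromosome 6 held 1.11 and 0.720 times (0.73 and 0.725). A diffuse IP signal without extra copies also stays open, since input tags per peak were 1.08 times those elsewhere on average, 1.22 (95% interval 1.05 to 1.41) in replicate 1 and 0.936 (0.697 to 1.24) in replicate 2. Peaks there were shared less often, 31.4% against 62.0% in replicate 1 and 55.0% against 72.3% in replicate 2 (Fisher's exact test, p = 6.24e-06 and 0.0392).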
